A study of Mus musculus with 1203 samples.

How the data were processed

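Single cells from the colon of female mice aged 11 weeks had been sorted by flow cytometry into well plates and profiled by Smart-seq2 with modifications, a plate method that copies polyadenylated RNA into full-length cDNA 1 cell at a time. The mice were wild type or carried Villin-Cre with floxed Ipmk alleles, which removes Ipmk, the gene for inositol polyphosphate multikinase, in intestinal epithelial cells. Each of the 1203 wells is a sample of its own, labelled by genotype and as a tuft cell (1083 wells) or an epithelial cell (120 wells). Per the labels' protocols, live cells were stained for EPCAM, an epithelial surface protein, and for SIGLEC-F, which marks tuft cells among them, and wells with late or no amplification of GAPDH cDNA were discarded. The gate used for the wells labelled epithelial is not given in the sources used here.

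The deposited values are TPM, length-normalised transcript shares scaled to a total of 1000000, for 46517 mouse genes and 92 spike-in entries in each well. That unit follows from the values: every non-empty column sums to between 999999 and 1000000. The submitters' processing notes name Bowtie2 2.4.2, RSEM 1.3.3 and build mm10, without their settings. The annotation release, the handling of strand and the read depth per cell are not given in the sources used here. TPM keeps no depth, so the number of genes above 0 stands in for it below. RSEM distributes reads among near-identical transcripts by a model, so values of pseudogenes and close paralogs are uncertain. The spike-in entries total 0 TPM. The entry for 18S ribosomal RNA, Rn18s-rs5, held 76.4% of all TPM on average (75.0% to 80.1% by plate set in the tuft gate), the 20 most abundant genes outside the mitochondrial genome 84.9%, and mitochondrial genes 4.19%. Because these share the fixed total, a level of 10 TPM is a strict floor for other genes in this table.

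Well titles give 16 plates in 7 plate sets. Plate sets 1, 3 and 6 are wild type and plate sets 2, 4, 5 and 7 are labelled conditional knockout, so no plate set holds both genotypes. No label names an animal. Each genotype is therefore 1 sample, no p-values were computed, and the SD given is that between plate sets, which may be technical. Cells with at least 1000 genes above 0 were kept, 856 in all; 19 wells hold no value. In the tuft gate these were 466 wild type cells, with 85, 109 and 272 in plate sets 1, 3 and 6, and 300 cells labelled conditional knockout, with 75, 106, 96 and 23 in plate sets 2, 4, 5 and 7. The 38 columns of 1 near-empty plate of plate set 7, with at most 6 genes above 0, were used only to count detected genes. No identical columns were found among the kept cells. No doublet caller was run. A well receives a sorted cell, and wells that received more than 1 cell were not searched for. The labels' genotype, cell type and plate set gave all groups.

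TPM was averaged over the cells of a plate set and gate, and log2(mean TPM + 1) was compared between genotypes with plate sets weighted equally, so differences of genes at low levels are understated. A gene met the rule of size when it reached 10 TPM in a genotype, differed at least 1.5-fold and had plate-set values that did not overlap between genotypes; 3 values against 4 fall apart this way in 5.71% of cases by chance. Tuft and epithelial wells share the first plate of each set and were compared within those 7 plates, with the same sign on every plate and at least a 2-fold difference required. Named are Ipmk and, by size among genes meeting the rule, the 12 highest and 12 lowest of the tuft genotype comparison, 5 and 5 of the epithelial one, and 10 and 10 between tuft and epithelial wells. Symbols of Gm plus digits, symbols ending in Rik, mitochondrial genes and entries without a symbol are counted but not named; 3 clone-named entries that met the rule are given by their values without their names, a choice made after seeing them. Some genes that met the rule are not reported here and were left out of the search for outlying plate sets. For 27 gene lists covering inositol phosphate kinases, tuft cell functions, cell stress, growth, interferon response and markers of other cell types, members with at least 1 TPM in a genotype were summarised by their median log2 difference, placed among 10000 random lists matched on mean expression in 50 bins. Random lists draw genes independently, so a list whose members vary together can reach an extreme place through a few cells or plate sets. The groups, comparisons, rule, lists, markers and most alternatives were fixed before the data were examined.

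Kept cells were clustered on log2(TPM + 1) of 2000 variable genes with 20 principal components, 15 neighbours and Leiden resolution 0.5. Clusters were named from the fixed marker lists. The scoring was chosen after seeing the data: a marker counted when at least 25% of a cluster's cells had it and its mean, with 10 TPM added, was at least 2-fold above the lower quartile of cluster means, and a cluster took the class with the largest share of its list counted, given at least 3 markers and 1 in 3 of the list, unless another class had more markers among the cluster's 10 leading genes. A cluster with far fewer genes detected than its plate sets also needed a marker among those 10. The tuft-like clusters held 493 cells, the colonocyte-like ones 135 and 62, and the stem or progenitor-like one 126. Shares of cells carry exact Clopper-Pearson 95% intervals, differences of shares Newcombe intervals, and a share of 0 the limit that 3 counts would give. All of these cover counting error only. Coordinates come from GENCODE M21 on GRCm38 (mm10), in which 46005 of the 46517 gene identifiers were found. In simulated plate sets drawn from wild type cells, the rule recovered 77.5% of 200 genes changed 2-fold among 2188 and 94.5% of 200 changed 4-fold among 2115, with 0 in the wrong direction, while 1.96% and 1.78% of unchanged genes met it. Cells were drawn at random from all wild type cells, so the simulated sets lacked the differences between real plate sets. Only genes at 2-fold the 10 TPM floor or more were changed, and these shares may not hold for the real comparison.

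Alternatives covered pseudocounts of 0.1 and 10 TPM, means of logs over cells, equal weight for cells, other filters on cells, on mitochondrial share and on low values, other folds, median-of-ratios scaling, leaving out mitochondrial and the 20 most abundant genes, the first or later plates alone, tuft-like cells alone, other clustering settings, and leaving out each plate set in turn. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9.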

Results

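Colonic tuft cells, rare chemosensory cells of the gut lining, were compared between wild type mice and mice with floxed Ipmk alleles and Villin-Cre, to ask how loss of this inositol phosphate kinase in the intestinal epithelium affects them. After the filter on detected genes, 78.98% of the wild type wells of the tuft gate and 60.9% of those labelled conditional knockout remained, the latter 300 cells. Plate set 7 gave only 23 of these. Wells labelled epithelial gave 39 wild type and 51 conditional knockout cells. Read depth is unknown from TPM. The median number of genes detected per tuft-gate cell was 2679 ± 201.6 over the wild type plate sets (SD, n = 3) and 2315 ± 460 over the others (SD, n = 4), a difference of −363 that lies within the SD of 378.3 between plate sets and was −177 without plate set 7.

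Ipmk, the targeted gene (a protein-coding gene, ENSMUSG00000060733, on chromosome 10 from 71347763 to 71433327, plus strand, GRCm38), was not lower in cells labelled conditional knockout. In the tuft gate its mean was 3.22, 4.31 and 3.31 TPM in the wild type plate sets 1, 3 and 6, and 6.90, 18.8, 9.63 and 7.57 TPM in plate sets 2, 4, 5 and 7, or 3.61 ± 0.60 (SD, n = 3) against 10.7 ± 5.52 TPM (SD, n = 4). The log2 difference was 1.25. Shares of cells with any Ipmk value were close, 28.1% in wild type cells (interval 24.1% to 32.4%) and 26.7% in cells labelled conditional knockout (21.7% to 32.1%). The median over cells with a value was 6.61 and 16.63 TPM. The highest single cell reached 523.7 TPM in plate set 4. Within tuft-like cells alone, 18.97% of wild type cells (14.6% to 23.96%) and 12.97% of cells labelled conditional knockout (8.49% to 18.7%) had a value, and the log2 difference was 0.16. With the mean taken over cells of log2(TPM + 1) it was 0.28, and 0.57 and 0.67 with a pseudocount of 10 TPM and on the first plates alone. In wells labelled epithelial the plate-set means were 8.26, 1.55 and 3.19 TPM for wild type and 34.2, 1.23, 9.41 and 5.85 TPM for conditional knockout. A gene-level TPM covers the whole transcript and does not read the deleted part alone, so these values neither show nor exclude the deletion, and directions given below are those of the labels.

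In tuft-gate cells labelled conditional knockout, genes of the interferon response were higher together. All 16 measured members of the fixed list lay above the wild type mean, 11 with no overlap between plate sets, and 6 met the rule of size. The list median was 1.25 on the log2 scale (SD between plate sets 0.38), above every one of the 10000 matched random lists. It was 0.39 with a pseudocount of 10 TPM, which weighs down genes at low levels, 0.53 with logs averaged over cells and 1.68 with a pseudocount of 0.1 TPM. Irf7, a transcription factor that amplifies type I interferon production, averaged 105.7 ± 31.7 against 27.5 ± 10.5 TPM. Oasl2 averaged 21.6 ± 0.78 against 5.57 ± 1.02 TPM and Bst2, a membrane protein that tethers budding viruses, 16.3 ± 2.45 against 4.32 ± 1.28 TPM.

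Their log2 differences were 1.94, 1.79 and 1.72. Oas2, an oligoadenylate synthetase outside the fixed list, differed by 2.23, and the list members Ifi27l2b and Oas1a by 1.34 and 1.20. The genes also stood higher within tuft-like cells alone, where Irf7 differed by 2.30, Bst2 by 2.28, Oas2 by 2.43 and Oasl2 by 1.57 and the list median was 1.14, with 17 of 17 measured members above the wild type mean. Oas1a differed by 1.14 there but its plate sets overlapped, at 7.27 TPM in plate set 7 against 8.54 TPM in plate set 3. Irf7 is also a member of the immune-type tuft list. No plate set holds both genotypes, so the plate set and the genotype cannot be told apart.

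**Figure D1:**
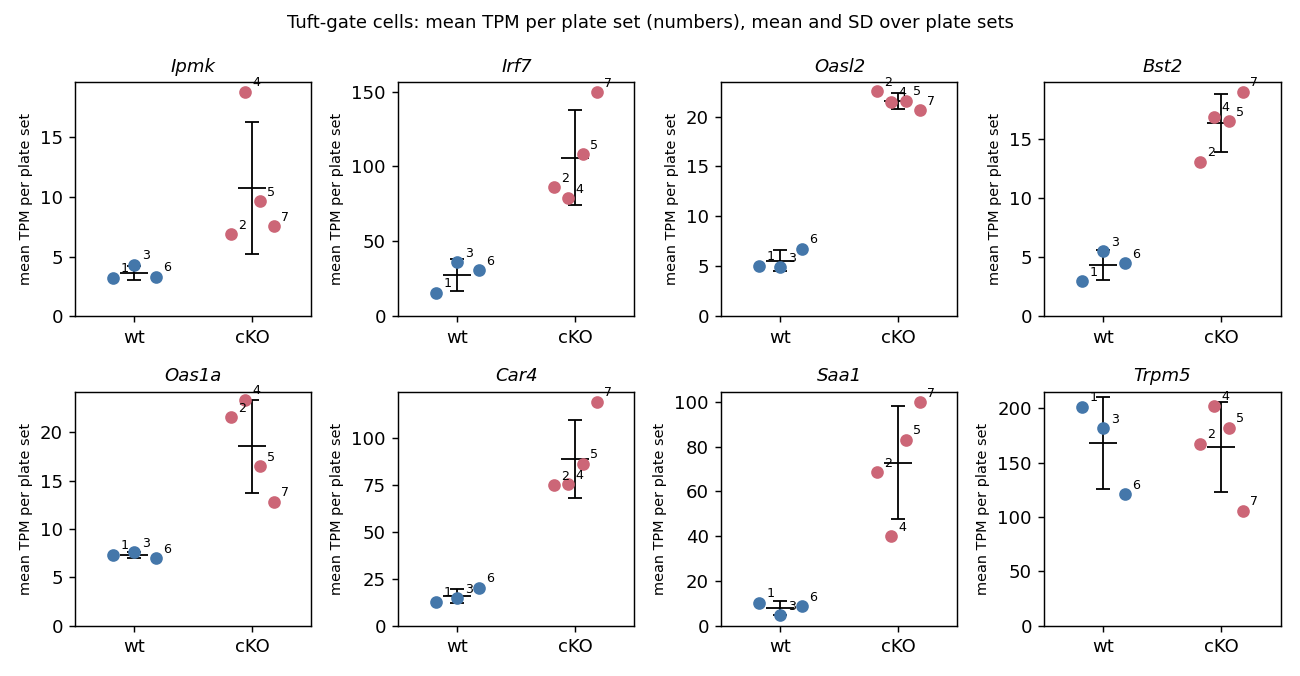
Mean TPM of 8 genes over the tuft-gate cells of each plate set, by genotype label; points are plate sets with their number, bars the mean and SD over plate sets. Ipmk, Irf7, Oasl2, Bst2, Oas1a, Car4 and Saa1 lie higher under the conditional knockout label with no overlap between the labels. Trpm5 overlaps.

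A second group of higher genes belonged to absorptive colonocytes. All 17 markers of these cells lay above the wild type mean in the tuft gate, 5 by the rule of size, with a list median of 0.88 (SD 0.82), which was 0.54 without plate set 7. Saa1, an acute phase protein, averaged 72.9 ± 25.3 against 7.88 ± 2.97 TPM, the water channel Aqp8 25.4 ± 17.9 against 4.09 ± 3.53 TPM and the carbonic anhydrase Car4 88.8 ± 20.9 against 15.9 ± 3.81 TPM. The chloride exchanger Slc26a3 differed by 1.71. Among the highest genes on none of the marker lists, the uridine phosphorylase Upp1 differed by 1.84, the small proline-rich protein gene Sprr2a1 by 1.81, Fhl1 by 1.54 and the kinase Tnk2 by 1.52, or 0.85 without plate set 4. None of these 8 genes met the rule within tuft-like cells, where Saa1 differed by −0.51, Aqp8 by −0.05, Car4 by 0.14, Sprr2a1 by −0.10, Slc26a3 by 0.23, Upp1 by 0, Fhl1 by 0.06 and Tnk2 by 0.21 (0.60 without plate set 7), and the list median was −0.32 over 5 measured markers. Saa1, Aqp8, Car4 and Slc26a3 averaged under 1 TPM there under both labels. They could therefore not reach the 10 TPM that the rule asks for, and their differences are values near the floor. Tuft-like cells were picked by clusters that colonocyte markers help to define, so small differences of those markers there partly follow from that choice. Colonocyte-like cells made up 19.1 ± 2.52% of tuft-gate cells over wild type plate sets (SD, n = 3) and 26.8 ± 15.6% over those labelled conditional knockout (SD, n = 4), from 10.7% in plate set 2 to 47.8% in plate set 7, or 19.8% on average without the latter. Wild type plate sets had at least 17.6%. Plate set 2 nevertheless had Saa1 at 68.5, Car4 at 74.6, Aqp8 at 19.2 and Slc26a3 at 9.38 TPM. Wild type plate sets reached at most 10.3, 20.1, 8.03 and 7.28 TPM. Whether the share of these cells accounts for the higher genes was not tested.

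Genes lower in tuft-gate cells labelled conditional knockout included Dtnb, a dystrobrevin of the dystrophin complex, with a log2 difference of −2.19, the vesicular amine transporter Slc18b1 (−2.16), Tmem39a (−1.91), the cyclin-dependent kinase Cdk6 (−1.90), the mitochondrial RNA-binding protein Slirp (−1.83) and Zfand5 (−1.64). Dtnb averaged 19.02 ± 15.3 TPM in wild type and 2.95 ± 1.57 TPM in cells labelled conditional knockout, and Cdk6 10.7 ± 3.94 and 2.46 ± 2.05 TPM. Slc18b1 rested on plate set 6, at 29.9 TPM against 3.31 and 3.17 in plate sets 1 and 3, and its difference was −1.20 without it. The ribosomal protein gene Rpl27 (−1.73), Tma7 (−1.67) and the splicing factor subunit Phf5a (−1.32) were near or at 0 in the 23 cells of plate set 7. So were the pseudogene Rpl30-ps9 (−2.16) and a clone-named entry (−2.21) that GENCODE M21 lists as a pseudogene. Without that plate set all of these differed, in the order given, by −0.81, −0.54, −0.52, −1.26 and −0.85. Another clone-named entry was listed at 0 in all 4 plate sets labelled conditional knockout and at 35.2, 19.9 and 1.77 TPM in plate sets 1, 3 and 6. Rpl27, Rpl30-ps9 and both clone-named entries have near-identical copies or lie in unsettled annotation, and their values are uncertain. Dtnb and Rpl27 alone among these 12 met the rule within tuft-like cells too. The others were still lower there, from −1.02 for Zfand5 to −3.59 for the second clone-named entry. Slc18b1 was at −2.56, Tmem39a at −2.49, Tma7 at −2.12, Slirp at −1.75 and Cdk6 at −1.60.

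Ribosomal protein genes were lower as a list, with a median of −0.54 (SD 0.46), which was below all but 0.05% of matched random lists and was −0.32 without plate set 7. Of 20 members 19 had a negative difference and 2, Rps6 (−0.62) among them, met the rule. In tuft-like cells the median was −0.53 and 6 met it, among them Rps18 (−0.83) and Rps4x (−0.80). Stem and progenitor markers had a median of −0.44 over 12 members, with Axin2 at −0.91 and Stmn1 at −0.93 and none meeting the rule. Within tuft-like cells it was −0.18 over 8 members, inside the central 95% of random lists, and plate set 7 held 0 stem or progenitor-like cells. The goblet cell list (−0.76, 13 members) and the MHC class II list (−2.23, 6 members) had SDs of 1.83 and 3.54 between plate sets, since a few cells carry these genes. Their medians were −0.15 and −1.13 without plate set 6. Without the others in turn the goblet list was −1.57 (set 5) and −0.30 (set 7), and the MHC class II list −1.18, −4.29 and −4.02 (sets 1, 3 and 4).

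Genes that define tuft cells showed no shift of that size. The cells had been sorted with a stain for the tuft cell marker SIGLEC-F. The 24 measured core tuft genes had a median of −0.07 (SD 0.33) and 0 met the rule; Trpm5, the taste channel, averaged 167.9 ± 42.04 against 164.4 ± 41.6 TPM and Dclk1 358.7 ± 102.7 against 321.8 ± 94.01 TPM. Medians were −0.04 for taste signalling (9 members), 0.02 for the neuronal-type tuft list (10 members, Rgs2 lower by the rule at −0.74), −0.22 for the immune-type list (11 members, Irf7 higher by the rule), −0.25 for acetylcholine genes (6 members, Chat at −0.39), −0.09 for eicosanoid genes (10 members, Alox5ap at −1.18 with an SD of 0.99) and −0.04 for the type 2 cytokine axis (7 members, Il25 at 0.95). Among the others, medians were 0.07 for inositol phosphate kinases (7 members, only Ipmk meeting the rule), −0.29 for the cell cycle (19 members), −0.25 for mTOR and AMPK (14 members), −0.04 for oxidative phosphorylation (18 members), −0.23 for mitochondrially encoded genes (13 members), −0.26 for Wnt and Notch (11 members) and −0.11 for tight junctions (14 members). None of the lists in these sentences left the central 95% of matched random lists in the whole gate. Within tuft-like cells the core tuft list, with a median of −0.02 where that of all genes was −0.25, lay above 99.7% of them. Those cells were picked by clusters named from that same list, so its place there partly follows from the choice. Early response and heat shock genes had a median of 0.28 (SD 0.49, 16 members), above 99.9% of random lists, with Btg2 higher by the rule at 0.77 and Socs3 at −0.71. That median was −0.01, 0.17 and 0.14 without plate sets 3, 4 and 7, 0.43 and 0.45 without plate sets 2 and 6, and −0.12 on the first plates alone. Within tuft-like cells it was 0.34, with 11 of 14 members higher and 0 by the rule, or −0.06 without plate set 7. The p53 and apoptosis list (0.11, 15 members, above 97.6% of random lists) was −0.04 within tuft-like cells and −0.02 without plate set 6. Lymphocyte and macrophage lists had 1 and 2 measured members, with Ccl5 listed at 0 in every plate set labelled conditional knockout and Lyz2 at −2.29 with an SD of 3.86. Enteroendocrine, eosinophil and stromal or endothelial lists had 0.

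**Figure D2:**
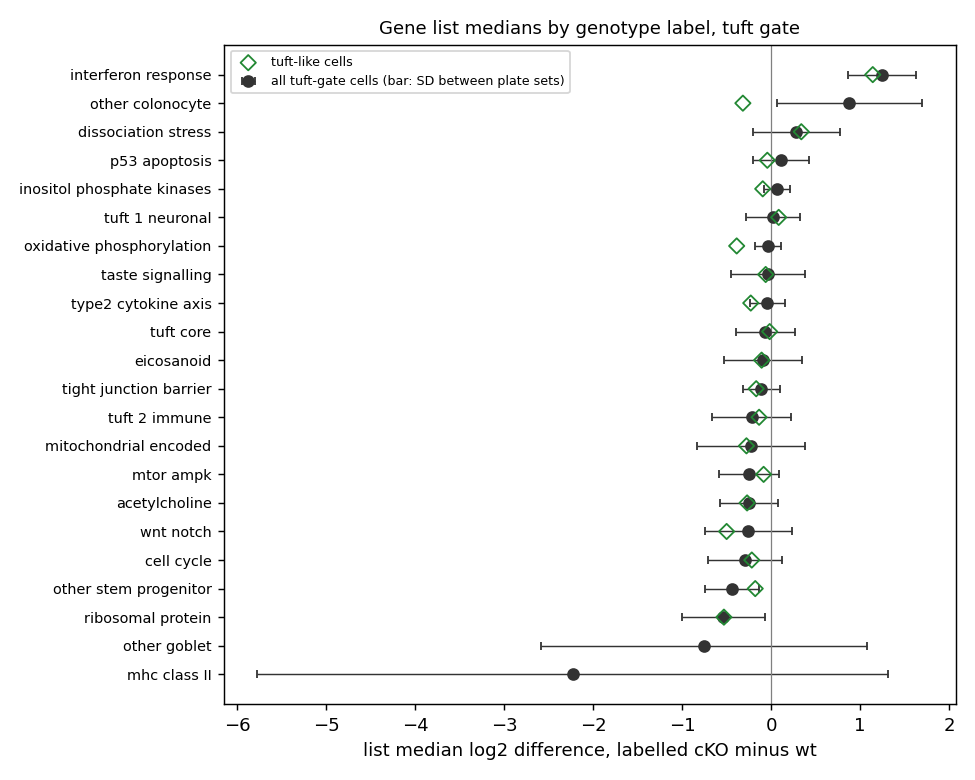
Median log2 difference of each gene list, cells labelled conditional knockout minus wild type; filled points are all tuft-gate cells with the SD between plate sets, open diamonds are tuft-like cells alone where at least 5 members were measured. The interferon list stands at 1.25 and 1.14, while the colonocyte list goes from 0.88 over 17 members to −0.32 over the 5 measured in tuft-like cells.

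By count, 44 genes (1.93%) were higher and 50 (2.20%) lower in tuft-gate cells labelled conditional knockout out of 2277 that reached 10 TPM, and plate-set values did not overlap for 6.02% of these genes, against 5.71% by chance. The median of all genes was −0.15. With a plate set left out more genes pass by construction, since chance non-overlap is 13.3% without a wild type plate set and 10% without another. Genes higher were 4.60%, 4.31% and 3.21% of those tested without plate sets 1, 2 and 7, and genes lower 5.13%, 4.25%, 5.37%, 4.03% and 9.23% without plate sets 2, 3, 4, 5 and 6. Genes without overlap were 0.73 to 1.35 times the share that chance gives, against 1.05 times with all plate sets. Within tuft-like cells 34 were higher and 74 lower, of which 15 and 19 were shared with the whole gate, and with the mitochondrial and 20 most abundant genes left out 2.23% were higher and 3.29% lower of 9666, which is 4.91 and 6.36 times as many genes.

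Clusters named from the fixed markers gave 4 tuft-like clusters, 2 colonocyte-like clusters, a stem or progenitor-like cluster, a goblet-like cluster with 32 cells and 8 unnamed cells led by Cd74, H2-Ab1 and Lyz2. Tuft-like cells were 63.4 ± 3.31% of the tuft gate over wild type plate sets (SD, n = 3) and 60.2 ± 5.996% over those labelled conditional knockout (SD, n = 4), a difference of −3.20 points that was less than the spread between plate sets and was −1.35, −5.37 and −0.53 without plate sets 1, 2 and 7. Cells had been sorted with a stain for SIGLEC-F, so these shares describe the sorted cells and not how many tuft cells the colon holds. The 4 tuft-like clusters held 26.9 ± 5.15%, 12.04 ± 1.51%, 12.4 ± 3.54% and 12.08 ± 2.84% of tuft-gate cells over wild type plate sets and 18.6 ± 9.54%, 22.03 ± 8.79%, 8.29 ± 3.13% and 11.2 ± 4.10% over those labelled conditional knockout. The second of these clusters ran from 10.6% to 13.6% and from 14.7% to 34.8%, and its cells had a median of 1512.5 genes detected, against 2498 to 4024 in the other tuft-like clusters. The third was led by Rpl35a pseudogenes. Pooled over cells, stem or progenitor-like cells were 14.2% (11.1% to 17.7%) and 12.3% (8.83% to 16.6%). Goblet-like cells were 3.86% (2.31% to 6.04%) and 2.33% (0.94% to 4.75%). The stem or progenitor-like cluster and the smaller colonocyte-like one also had Trpm5 in 56.3% and 85.5% of their cells, at 42.4 and 31.8 TPM on average against 177.3 to 316.4 TPM in the tuft-like clusters, and their names change with the clustering settings.

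In wells labelled epithelial, the genes named by size included goblet cell genes among those higher and tuft cell genes among those lower under the conditional knockout label. Zg16, a goblet cell secretory protein, was listed at 0 in all wild type plate sets and at 10.1, 110, 7252 and 97.8 TPM in plate sets 2, 4, 5 and 7. Agr2, a disulfide isomerase of mucus-secreting cells, averaged 495.2 ± 350.6 against 6.17 ± 6.24 TPM, and the surface protein Ly6a 72.2 ± 42.1 against 4.96 ± 7.88 TPM. Mptx1 was listed at 0 in wild type and at 8.37, 279.8, 114.2 and 8.49 TPM, and the glycosyltransferase B3gnt7 at 0 in wild type and at 14.9, 38.3, 4.91 and 10.1 TPM. The tuft cell genes Dclk1 and Sh2d6 averaged 282.3 ± 259.9 and 189.1 ± 212.3 TPM in wild type and 7.22 ± 14.4 and 3.45 ± 6.91 TPM under the conditional knockout label. A clone-named entry and Rps24-ps3 were listed at 0 in all 4 plate sets labelled conditional knockout and at 247.3, 17.5 and 27.7 and at 83.3, 35.6 and 12.2 TPM in plate sets 1, 3 and 6. GENCODE M21 lists both as pseudogenes, and their values are uncertain.

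Tuft-like cells were 18 of the 39 wild type wells labelled epithelial (46.2%, interval 30.1% to 62.8%), as 1 of 6, 4 of 13 and 13 of 20 in plate sets 1, 3 and 6, and 0 of 51 under the conditional knockout label, which allows a share of up to 5.88%. Goblet-like cells were 0 of 39, allowing up to 7.69%, and 7 of 51 (13.7%, 5.70% to 26.3%). By the rule 110 genes (3.24%) were higher and 5.84% lower of 3393, and 9.22% of genes had no overlap between plate sets, against 5.71% by chance. Outside tuft-like cells 76 (2.20%) were higher and 4.73% lower of 3447, and the share with no overlap was 7.22%, nearer to chance. There Dclk1 did not meet the rule, at −1.99. The goblet list had a median of 2.88 (13 members, SD 2.94, 2 higher by the rule) and the core tuft list −0.77 (19 members, SD 2.01, 0 by the rule). Medians were −0.63 for the colonocyte list (17 members, SD 1.10, 2 lower by the rule) and 0.40 for the interferon list (17 members, SD 1.04, 0 by the rule). The cell cycle list had 0.57 (20 members, SD 1.32, 0 by the rule). Plate sets hold 6 to 20 cells labelled epithelial. Over all of these cells, with the same rise in chance non-overlap, genes higher were 8.47%, 5.33%, 7.69% and 5.09% of those tested without plate sets 1, 2, 3 and 7, and genes lower 10.4%, 8.72% and 20.3% without plate sets 1, 2 and 6. Genes without overlap were 1.16 to 1.88 times the share that chance gives, against 1.61 times with all plate sets.

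Between tuft and epithelial wells of the same plates, Atp2b4, a plasma membrane calcium pump, was higher in tuft wells by 8.25 on the log2 scale (778 against 17.9 TPM), followed by Kctd12 (3.02), the integrin regulator Fermt1 (2.79), the anion transporter Slco4a1 (2.29), St6galnac2 (1.82), the DNA methyltransferase Dnmt3a (1.76), Bst2 (1.73), the tubulin acetyltransferase Atat1 (1.66), Chdh (1.58) and Dtnb (1.57). Lower in tuft wells were the surface keratin gene Krt20 (−1.997), Rdm1 (−1.98), Srp9 (−1.80), the cytochrome P450 Cyp3a13 (−1.78), N6amt2 (−1.78), Clec2h (−1.70), the water channel Aqp4 (−1.70), Sft2d1 (−1.69), Agpat4 (−1.69) and Pdzk1ip1 (−1.65). Core tuft genes were higher with a median of 2.70 and the same direction in 23 of 24, immune-type tuft genes with 2.79 in 11 of 11, and colonocyte markers lower with −1.09, 4 by the rule. No core tuft gene met the rule, since it asks for the same sign on all 7 plates. On plate set 6, 13 of 20 cells labelled epithelial were tuft-like. There the named genes higher in tuft wells differed by 1.20, 0.30, 3.40, 0.48, 0.03, 1.71, 0.18, 0.30, 0.20 and 0.04, in the order given. The named lower ones differed there by between −0.0035 (Krt20) and −1.27 (Aqp4).

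The rule was met by 20 genes (0.68%) higher and 70 (2.37%) lower in tuft wells of 2954, where a given direction on all 7 plates has a chance of 1.56% for both directions together. They were 3.73% and 19.5% of the genes tested without plate set 6, genes higher were 31 and 37 without plate sets 1 and 3, and genes lower 3.91% without plate set 4, where 1 direction on 6 plates has a chance of 3.125%. Genes of 1 direction were 9.62 times that chance without plate set 6 and 2.02 to 2.60 times without another, against 3.40 times on all plates. When tuft wells were limited to tuft-like cells and epithelial wells to the rest, 7.27% were higher and 23.04% lower of 3203, and 21 of 24 core tuft genes, 7 of 11 immune-type genes and 11 of 17 colonocyte markers met the rule, with medians of 4.87, 4.65 and −5.56. In that comparison Trpm5 averaged 267.6 against 3.51 TPM, Chat, which makes acetylcholine, 16.02 against 0.38, and Krt20 0.20 against 177.8 TPM. These cells were chosen by clusters that core tuft and colonocyte genes help to define, so these values describe the clusters. Fermt1 differed by 0.33 there, against 2.79 between the gates, and by −0.67 between the gates with means of logs over cells.

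**Figure D3:**
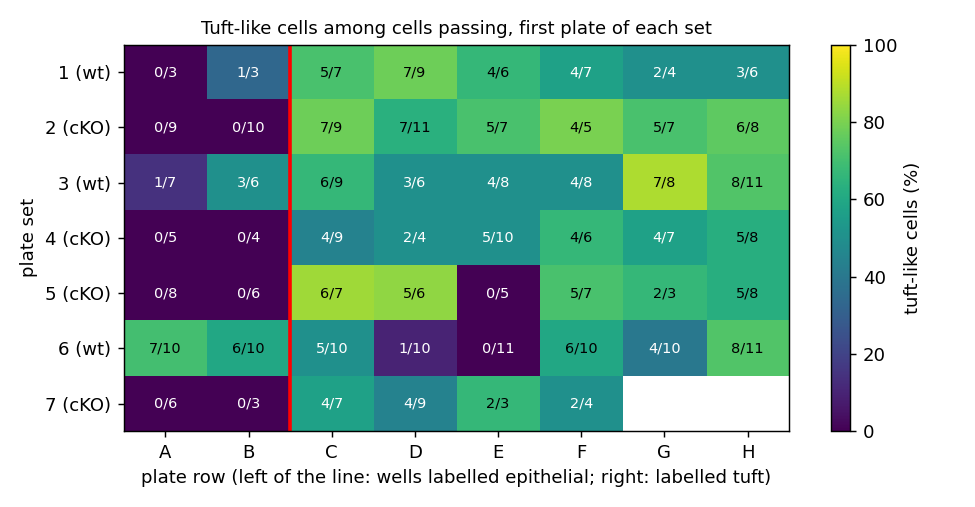
Share of tuft-like cells among cells passing, by plate row (columns A to H) of the first plate of each plate set; cells show tuft-like over passing cells, and the line separates wells labelled epithelial from wells labelled tuft. On plate set 6, 13 of 20 cells left of the line were tuft-like, against 0 in the plate sets labelled conditional knockout.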

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

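In this part the comparison of first and later wild type plates was set before its result was seen, while the tests within plate sets 1, 3 and 6 and without plate set 6, the look at pairs of plate rows and the test of the sorting gate were chosen afterwards. Each group of 4 plate sets or 7 plates behind a named value was searched for a member far from the rest, 84 groups in all, and 9 were found. The search used Dixon's ratio, the gap to the nearest member over the range. Its limit of 5% by chance holds for normal values, and the chance share for these means is unknown. A group at 0 in all members but 1 always passes. Aqp8 stood at 52.1 TPM in tuft-gate cells of plate set 7, against at most 19.2 in the other plate sets labelled conditional knockout, and Tnk2 at 37.98 TPM in plate set 4, against at most 5.78. In wells labelled epithelial, Zg16 reached 7252 TPM in plate set 5, with 110.4 as the next value. Plate set 4 had 28.9 TPM of Dclk1 and 13.8 of Sh2d6 in those wells, where the other plate sets of that label had 0 of both. The immune-type tuft list had its lowest median log2(TPM + 1), 3.87, in the 23 cells of plate set 7, with 4.78 as the next value. The MHC class II list stood at 7.23 in plate set 4, against at most 0.57, and that plate set held all unnamed cells of its label, 2.83% of its tuft-gate cells against 0% elsewhere. Atp2b4 differed between tuft and epithelial wells by 1.20 on plate set 6 and by at least 7.96 on the other plates. Of 34 genes compared between the genotype differences of tuft and epithelial wells, 0 went opposite ways in every plate set.

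Tuft-like cells in wild type wells labelled epithelial bear on the cell type labels. An exchange of wells between the gates may account for them on plate set 6: it would leave as many tuft-labelled wells without tuft-like cells, and on wild type first plates 53.6% of tuft-gate cells were tuft-like against 66.3% on later plates, a difference of −12.7 points (interval −22.1 to −3.26) where a full exchange needs −11.9, while under the conditional knockout label it was 0.67 points (−10.2 to 11.5). The wild type value rests on plate set 6, and without it was −0.72 points (−14.1 to 12.5) with −5.62 needed. Within plate set 6 it was −28.4 points (−41.1 to −14.3), with −20.97 needed, and on its first plate 13 of 20 cells in rows A and B but 1 of 21 in rows D and E were tuft-like. Plate set 1 gave −5.46 points (−24.8 to 14.02) with −2.56 needed and plate set 3 gave 2.98 points (−14.96 to 20.4) with −8 needed, and their cells are too few to decide. The sorting gate of the epithelial wells also stays open, since it is not described and 0 plate sets hold both genotypes, a difference of genotype was not tested, and no well was relabelled for any value given here.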

How the results depend on the processing

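No paired analysis was possible because, for genotype, each plate set holds 1 genotype and replicate numbers only name cells; tuft and epithelial wells were compared within plates. The settings of tuft-like cells without plate set 7, without the first plate of plate set 6 and with a 50 TPM floor after the most abundant genes were left out, and the splits in tuft-like cells and in rescaled values, were chosen after seeing the data. The interferon (0.39 to 1.68), ribosomal protein (−0.83 to −0.21) and stem or progenitor (−0.63 to −0.15) lists kept their direction under all 21 settings run on lists. The MHC class II list gave no value in tuft-like cells, nor the mitochondrial list with its genes left out. The cause of the shifts was not tested, except that by construction higher floors and folds leave fewer genes and fewer plate sets leave more. Chance non-overlap, 5.71% with all plate sets, is 13.3% without a wild type one and 10% without another, as on later plates, and 1 direction on 6 plates has a chance of 3.125%, against 1.56% on 7. Read depth is unknown from TPM, so no value can be weighed by it. Counts are given as percent of genes tested.

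Genes higher and lower in tuft-gate cells labelled conditional knockout, 1.93% and 2.20% of 2277, were 1.23% and 1.36% with a pseudocount of 10 TPM, 1.14% and 1.01% at 2-fold, 0.65% and 1.3% of 21998 with no floor (3.23 and 5.72 times as many genes), 2.31% and 3.94% at 50 TPM (10 and 17 genes), 2.23% and 3.29% of 9666 with the mitochondrial and most abundant genes left out, and 2.91% and 2.84% of 4015 with a 50 TPM floor there. Genes higher were 1.19% with logs averaged over cells, 2.57% with at least 2000 genes per cell, 4.45% on later plates and 2.99% by non-overlap alone. Genes lower were 5.09% with no filter on cells, 3.76% on first plates and 3.81% in tuft-like cells without plate set 7. With a plate set left out they ran from 2.08% to 4.60% and from 1.91% to 9.23%. Splits with as many genes numbered 14 of 35, but 2 with median-of-ratios factors, 4 at 2-fold and 6 in the rescaled values.

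Lists outside the central 95% of random lists numbered 8, but 4 with no filter on cells and in tuft-like cells, 3 there without plate set 7, and 6 to 11 with a plate set left out. The Ipmk difference of 1.25 was 0.57 with a pseudocount of 10 TPM, 0.28 with logs averaged over cells, 0.67 on first plates, 0.16 in tuft-like cells, 0.38 there without plate set 7, and 0.97 to 1.41 with a plate set left out. Directions turned for the p53 list (−0.10 with no filter on cells, −0.021 rescaled, −0.044 in tuft-like cells, −0.021 to 0.25 with a plate set left out), the early response list (−0.12 on first plates, −0.055 in tuft-like cells without plate set 7, −0.0059 to 0.45 with a plate set left out), the goblet list (0.16 with at least 2000 genes, 0.52 on later plates, 0.43 in tuft-like cells, 0.21 there without plate set 7), the MHC class II list (0.25 on later plates) and the colonocyte list (−0.32 in tuft-like cells). In tuft-like cells Saa1, Aqp8 and Sprr2a1 were at −0.51, −0.049 and −0.10, and at −0.51, −0.021 and −0.082 without plate set 7. Saa1 and Aqp8 averaged under 1 TPM in tuft-like cells under both labels, so their signs there are read near the floor.

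In wells labelled epithelial 3.24% and 5.84% became 5.87% and 3.45% with logs averaged over cells, 1.62% and 3.03% of 16346 with no floor, 2.96% and 4.70% at 50 TPM (22 and 35 genes), and 3.60% to 8.47% and 6.32% to 20.3% with a plate set left out. Between tuft and epithelial wells 0.68% and 2.37% became 0.10% and 0.47% with a pseudocount of 10 TPM, 0.98% and 3.28% with at least 2000 genes, 7.27% and 23.04% by cluster, and 0.73% to 3.73% and 2.58% to 19.5% with a plate set left out; genes higher were 0.17% with logs averaged over cells, where Fermt1 was at −0.67. The difference in genes detected ran from −536.3 to −177 and that in tuft-like share from −5.37 to −0.53 with a plate set left out. Among named tuft-gate genes, 75 other log2 values moved by more than 1 SD between plate sets in the same direction.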

Other observations

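In this part the splits of plate sets for wells labelled epithelial and the exchange of gates within plates were set before their results were seen, and the other tests, on interferon genes, on gene counts in the tuft gate and on Ipmk, were chosen afterwards. Tuft-like cells of tuft wells differed from the other cells of epithelial wells on the same plates in several fixed lists, some of whose members are also cluster markers. Taste signalling genes were higher with a median log2 difference of 3.51, 6 of 9 by the rule, eicosanoid genes with 1.60, 5 of 10, and the neuronal-type tuft list with 1.83, 2 of 10. Early response and heat shock genes were lower with a median of −2.15, 9 of 15 by the rule, as were oxidative phosphorylation genes (−1.46, 10 of 18) and tight junction genes (−1.40, 6 of 14). Cell cycle genes had negative differences in all 19 measured members with a median of −1.65, though 0 met the rule, and ribosomal protein genes had −1.07 with 2 of 20. Medians were −0.12 for inositol phosphate kinases and −0.09 for the mTOR and AMPK list. These cells were picked by clusters that such genes help to define. In all cells of the same wells the taste list had 1.83, early response genes −0.86 and oxidative phosphorylation −0.78, with 0 by the rule, and by cluster 7.27% of genes were higher and 23.04% lower by the rule, against 0.68% and 2.37%.

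The tuft gate also held a group of 8 cells, 5 wild type and 3 labelled conditional knockout, with Cd74 at 13450 TPM on average and in 100% of them, led besides by H2-Ab1, Lyz2, Cd52 and Tyrobp, and with Trpm5 and Dclk1 in 0%. The 18 tuft-like cells in wild type epithelial wells had Trpm5 at 205.7 TPM, Dclk1 at 768.7 and Siglecf at 109.4, against 224.1, 503.6 and 59.6 in tuft-like cells of wild type tuft wells. Medians of Siglecf over those cells were close, at 31 and 30.5 TPM.

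Interferon genes stood higher under the conditional knockout label in the cell classes compared over both gates, with a list median of 1.18 in tuft-like cells (17 of 17 members above wild type), 1.24 in colonocyte-like cells (17 of 17) and 0.83 in all cells outside the tuft-like clusters (15 of 16), but 0.40 with an SD of 1.04 in wells labelled epithelial without tuft-like cells. The median of 1.14 in tuft-like cells of the tuft gate argues against other cell types in the gate as the whole cause, and 1.46 with the mitochondrial and 20 most abundant genes left out against a few genes taking most of the TPM. Of the 35 splits of plate sets, 1 gave a median as large as the real 1.25, the real one itself, with 1.03 as the highest other, and in tuft-like cells 2 did (1.14 against 1.22 as the highest other). Chance cannot be excluded by these splits: plate sets may share an animal, 1 of 35 is the lowest share possible and the list was picked for its size. Plate set, animal or housing cannot be told apart from genotype, because 0 plate sets hold both. Loss of the kinase may raise these genes, which stays a hypothesis that this design leaves untested.

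Counts of genes were less distinct. As many as the real 94 genes were found in 14 of 35 splits of the plate sets, with 1.82 times that number as the highest other (plate sets 1, 3, 4 and 5 against the rest), so chance cannot be excluded. In tuft-like cells 11 of 35 splits gave as many as the real one. The same split gave 3.56 times the real number there, picked as the highest of the others, and its cause was not tested. That split was not the highest under every setting: with median-of-ratios factors, at 2-fold and with the abundant genes left out, plate sets 1, 2, 3 and 6 against the rest gave the most. They gave 1.64, 1.45 and 1.31 times the real number. For wells labelled epithelial, 3 of 35 splits gave as many as the real 3.24% higher and 5.84% lower together, with 1.40 times that number as the highest other, and chance cannot be excluded. For tuft against epithelial wells, 3 of 64 exchanges of the gates within plates gave as many as the real 90, the real one among them. Exchanging plate set 6 alone gave 6.17 times as many, and exchanging plate sets 6 and 7 gave as many. That share of exchanges was under the limit set beforehand, which would count against chance. The real labels were nevertheless not the extreme ones. On plate set 6, 13 of 20 cells labelled epithelial were tuft-like. Chance is not called excluded by this count, a reading more cautious than that limit.

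Higher Ipmk under the conditional knockout label was found mainly outside the tuft-like clusters. There plate-set means were 5.31, 8.68 and 5.94 TPM for wild type and 13.1, 39.9, 23.8 and 14.8 TPM for the other label, while within tuft-like cells the log2 difference was 0.16, or 0.38 without plate set 7, against 1.25 in the whole gate. Cells outside the tuft-like clusters are a candidate source, as a hypothesis. Whether a few cells with high values make up the difference stays open. Without the 5 and the 10 highest cells of each label it was 1.07 and 0.92 with no overlap between plate sets, but 0.20 with overlap without the 5 highest of each plate set, which leaves 1 of the 6 cells with a value in plate set 7. Exchanged genotype labels stay open: the share of cells with a value differed by −1.44 points, and a value for the deleted part alone was not analysed here. No biological explanation was tested.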
